A study of Drosophila melanogaster with 58 samples.

How the data were processed

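Embryos of Drosophila melanogaster were compared on 2-colour arrays in 2 experiments. In the gain-of-function experiment, embryos from the cross of the MZ1060 Gal4 line to the UAS-gcm line, which express gcm ectopically, were compared at stages 9 to 16 with a pool of equal amounts of RNA from both parental lines (33 arrays). In the loss-of-function experiment, homozygous gcm mutants, sorted by their lack of GFP, were compared at stages 10 to 14 and 16 with OregonR embryos treated alike (25 arrays). According to the series design text, the mutant stock carried a Kr-GFP balancer for stages 10 to 13 and a Ubi-GFP balancer for stages 14 to 16, so the marker whose absence picked homozygotes changed within the late stages.

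The deposited values are log2 ratios of Cy5 over Cy3, 1 per spot, with 1 column per array. The series design text states that the authors scanned the arrays with ScanArray software 3.1 and quantified them with GenePix 5.0. It also states that arrays were kept by the reproducibility of their repeat spots, with an SD limit of 0.333 on the log ratio. No statement on background correction or normalization was found there. The base of the logarithm was read from the values, which peak at the logarithms of small ratios to base 2, and the direction from the design text. The deposited arrays were not centred: their medians lay between -1.33 and 1.24 in the gain-of-function experiment and between -2.00 and 0.66 in the loss-of-function experiment. The table held 0 value columns other than the 58 used. It gives ratios without intensities, so neither an intensity-dependent correction nor a filter on signal over background could be applied.

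Each array held 47616 spots in 48 print blocks of 992, and each of the 23808 probes had its repeat spot 1984 spots later. Exact zeros, which filled 1.65% to 60.3% of the spots of a gain-of-function array and 3.63% to 39.5% of a loss-of-function array, were taken as missing, as were log2 values of 9 or more in size, which sit at fill values. The spots of a probe were averaged, each array was centred on its median, and ratios were turned to perturbed over wild type. The dye orientation came from the sample labels. As a check of it, 33 of 35 pairs of arrays with the same orientation correlated positively across probes within their stage before turning (median rho 0.19), and 54 of 57 pairs with opposite orientation correlated negatively (median rho -0.12). The 3 exceptions were replicates 1 and 4 of loss-of-function stage 12 (0.145), 1 and 4 of gain-of-function stage 16 (0.0300) and 1 and 3 of gain-of-function stage 13 (0.000766). The 2 negative pairs of the same orientation were replicates 1 and 2 of gain-of-function stage 13 (-0.0560) and 2 and 3 of loss-of-function stage 11 (-0.0502). Replicate 4 of loss-of-function stage 12 correlated with replicate 3, of its own orientation, at 0.216 and with replicate 2, of the other, at -0.00257, so its orientation is less sure than that of other arrays and was kept as labelled.

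Gene names came from the platform annotation supplied with the series, updated through Entrez identifiers to the RefSeq annotation of the Release 6 plus ISO1 MT assembly, which was used only for names and for which genes neighbour each other. Of the probes, 13455 had 1 gene, 153 had several and 10200 had none. The 13455 probes stood for 11663 genes. Of them, 12851 were found in the reference through their Entrez identifier, and 604 were not and kept the name of the platform annotation. For the 1383 genes with several probes, the probe measured on most arrays was used, then the first.

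One linear model was fitted per probe to all 58 arrays by least squares in R 4.3.3 (with version 1.17.8 of data.table), with 14 coefficients for the groups of experiment and stage and a dye term for each experiment, 16 in all. Variances were moderated with limma 3.58.1 (squeezeVar), so that each group drew on the spread of all arrays. Contrasts were computed from each probe's observed arrays, and p-values were two-sided with Benjamini-Hochberg adjustment within a comparison and a threshold of 0.05. A probe was tested in a group when at least 3 arrays and both dye orientations had measured it. The comparisons were each stage against 0, the mean of the stages of each experiment, late minus early stages (13 to 16 minus 9 to 12 in the gain of function, and 13, 14 and 16 minus 10 to 12 in the loss of function), gain minus loss of function over the 6 stages in both, and the overlap of both averages by Fisher's exact test. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

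The model was tested on simulated data with the observed residual spread, missing values and design, on 12223 probes of which 200 were changed. For the gain-of-function average, 55 of 100 probes changed by a log2 of 0.5 and 93 of 100 changed by a log2 of 1 were recovered, with 3.9% of calls false. For the loss-of-function average, 42 and 91 of 100 were recovered, with 2.21% false. For gain-of-function stage 9, 3 and 28 of 100 were recovered, with 3.12% false, and for loss-of-function stage 10, 5 and 45 of 100, with 7.41% false. On 5937 probes without missing values, the results equalled those of limma's own fit. The number of arrays, 4 or 5 per stage, limits the precision of single-stage values.

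Before the data were examined, 19 gene lists were fixed: gcm and gcm2, glia, neuronal differentiation, neuroblasts, neuronal identity factors, blood cells, tendon, muscle, cuticle and epidermis, trachea, midline, fat body and gut, cell cycle, Notch targets, apoptosis, maternal germ line, heat shock, ecdysone timing and ribosomal proteins. A further 2 lists, of maternal transcripts and of zygotic genes of the cellularising embryo, were added after the most changed genes had been seen. Lists with at least 4 measured members were tested with limma's cameraPR at an inter-gene correlation of 0.01 and again with the correlation estimated from the residuals, with Benjamini-Hochberg adjustment over the fixed lists and over the added lists apart. The fixed lists were also adjusted over the list alone.

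The rule for named genes was fixed before the data were examined as well. It took gcm, gcm2 and repo at every comparison. For each average it took the 12 highest and the 12 lowest genes past the threshold with the same sign on at least 80% of the arrays. For late minus early it took the 5 highest and 5 lowest, and for each stage the 2 highest and 2 lowest. Of genes past the threshold in both averages in opposite directions it took up to 8 each way, and from each list up to 4 members with the smallest adjusted p. The text gives all genes of this rule for the label genes, the averages, late minus early and the opposite changes. Of the genes of single stages and of the lists it names only a part, and that part was chosen after the values were seen. An earlier choice had left out genes whose calls depended on single arrays, and these were put back. Of the genes named, loco lies outside the rule, and its averages were chosen after they were seen.

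The alternatives fixed beforehand were arrays not centred, arrays scaled to one spread, no dye term, a replicate block, probes measured on every array, no filter on missing values, array weights, a robust prior, spot pairs with an SD under 0.333, values not turned for the dye, the arrays of 1 experiment or of 1 stage alone, and each array left out in turn. After the data had been seen, 6 more were added: zeros kept, log2 values of 5 or more in size left out, print blocks centred, arrays lacking over 40% of the probes left out, the mean of the added maternal list on each array as a covariate, and the arrays of gain-of-function stage 9 left out, with averages over the other stages. In other splits of the arrays, dye orientations, stages or experiments were permuted, with 100 splits drawn or every split where fewer existed. No array was left out of the values given as results.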

Results

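The data followed transcript levels in Drosophila embryos with too much or too little gcm, which encodes the transcription factor glial cells missing, a switch between neuronal and glial fate that also acts in blood cells. The gain-of-function experiment held 33 arrays, with 5 at stage 14 and 4 at each other stage from 9 to 16. The loss-of-function experiment held 25 arrays, with 5 at stage 10 and 4 at each of stages 11 to 14 and 16. Every ratio set perturbed embryos against wild type of the same stage on the same array, and both dye orientations were used at every stage. A gain-of-function array measured 11990 to 23100 of the 23808 probes (median 93.2%), and a loss-of-function array 10820 to 23250 (median 91.8%). Across the probes of an array, repeat spots correlated with a median rho of 0.337 and 0.379. Arrays lacking over 40% of the probes were replicate 1 of gain-of-function stage 9 (49.6% missing), replicate 2 of gain-of-function stage 14 (40.9%) and replicate 4 of loss-of-function stage 11 (54.5%). The wild types differed between the experiments, a pool of both parental lines in one and OregonR in the other.

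The first question was whether the manipulations changed gcm itself. With ectopic expression, gcm RNA averaged 2.54-fold higher than in the pooled wild type (log2 1.35 ± 0.10 SE, n = 33 arrays, higher on 31, adjusted p = 8.42e-15). Its log2 ratio was 0.13 ± 0.27 (SD, n = 4) at stage 9, 0.92 ± 0.37 (n = 4) at stage 10 and 1.13 ± 0.33 (n = 4) at stage 11, and its means lay between 1.45 and 1.88 from stage 12 to stage 16. In the mutants gcm RNA averaged 1.93-fold lower (log2 -0.95 ± 0.12 SE, n = 25 arrays, lower on 23, adjusted p = 1.03e-08), with -1.49 ± 0.43 (SD, n = 5) at stage 10 and -1.21 ± 0.71 (n = 4) at stage 11. The position of the gcm probe relative to the mutant lesion is not given in the sources used here, and RNA in the gain-of-function embryos can include that of the transgene.

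Replicate 4 of loss-of-function stage 12 had 0.74 for gcm, which lay below 0 on the other 3 arrays of that stage, with 1.02 for loco and -0.98 for repo. Without it the average of gcm was -0.99, gain minus loss was called at 2539 probes and opposite changes numbered 462, the highest of the counts with 1 array left out. In the limma model, gcm passed the threshold at gain-of-function stages 11 to 16 and at loss-of-function stages 10, 11, 14 and 16. It did not pass at gain-of-function stages 9 and 10 (adjusted p = 0.876 and 0.0548) or at loss-of-function stages 12 and 13 (log2 -0.30 and -0.63, adjusted p = 0.66 and 0.181). The call for gcm at gain-of-function stage 11 was lost without replicate 1, 2, 3 or 4 (log2 0.93, 1.11, 1.23 and 1.23). In the mutants, the stage 11 call was lost without replicate 2 (-1.02), the stage 14 call without replicate 1, 2 or 4 (-0.72, -0.96 and -1.12) and the stage 16 call without replicate 2, 3 or 4 (-0.50, -0.99 and -1.08), with -1.67 without replicate 1. On arrays not centred, gcm no longer passed at gain-of-function stages 11, 12, 13, 14 and 16 and loss-of-function stages 14 and 16. Its loss-of-function stage 14 call was also lost on scaled arrays (adjusted p = 0.0567), with no dye term (0.0593), with array weights (0.0513) and on the arrays of this experiment alone (0.323). The same held with zeros kept (adjusted p = 0.115), without arrays lacking over 40% (0.0511) and without gain-of-function stage 9 (0.0523). That at stage 16 was lost on scaled arrays (adjusted p = 0.0556), with no dye term (0.0869), on spot pairs with an SD under 0.333 (0.108), on the arrays of this experiment alone (0.283) and with zeros kept (0.123). That at stage 11 was lost on the arrays of this experiment alone (adjusted p = 0.0572). With the mean of the added maternal list as a covariate, gcm did not pass at gain-of-function stages 11 and 12 (adjusted p = 0.197 and 0.087). Its log2 ratio there was 1.01 ± 0.34 (SE) against 1.13 ± 0.29 without the covariate, and 1.45 ± 0.37 against 1.586 ± 0.29. At gain-of-function stage 10 it passed on scaled arrays (adjusted p = 0.0152), on probes measured on every array (0.047), with array weights (6.89e-05), on spot pairs (0.00646), on the arrays of this experiment alone (0.00341), with print blocks centred (0.0258) and with values of 5 or more left out (0.05 as rounded). At loss-of-function stage 13 it passed with array weights (adjusted p = 0.0443). Zeros kept, values of 5 or more left out, print blocks centred, the covariate and the fit without arrays lacking over 40% were alternatives chosen after the data were seen. The paralogue gcm2 had a log2 ratio of -0.04 ± 0.19 (SE, n = 32, adjusted p = 0.914) with ectopic gcm and of -0.59 ± 0.22 (n = 25, lower on 14, adjusted p = 0.0372) in the mutants. That mutant value no longer passed when any 1 of 11 arrays was left out, with the smallest change, -0.40, without replicate 2 of stage 13, nor on arrays not centred (-0.44). It did not pass either with no filter on missing values (adjusted p = 0.0543), on the arrays of this experiment alone (0.182) or with zeros kept (0.0784). Nor did it with values of 5 or more left out (adjusted p = 0.122) or with the maternal covariate (0.37). At single stages gcm2 passed only at loss-of-function stage 13 (-1.93 ± 0.54 SE, n = 4, adjusted p = 0.0142), a call lost without replicate 2 (-0.95), on arrays not centred (-1.48) and on arrays scaled to one spread (-1.49). That call was lost too on the arrays of this experiment alone (adjusted p = 0.161), with values of 5 or more left out (0.0646) and with the maternal covariate (0.166). At no single stage did repo pass, with log2 ratios from -0.17 at stage 9 to 0.58 at stage 15 with ectopic gcm and from -0.18 at stage 11 to 0.26 at stage 14 in the mutants. With array weights repo passed at gain-of-function stages 12, 14, 15 and 16 (0.46, 0.57, 0.36 and 0.52). It passed on spot pairs at stages 12 to 16 (0.41, 0.49, 0.42, 0.58 and 0.55) and on scaled arrays at stages 14 and 15 (0.55 and 0.69).

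**Figure D1:**
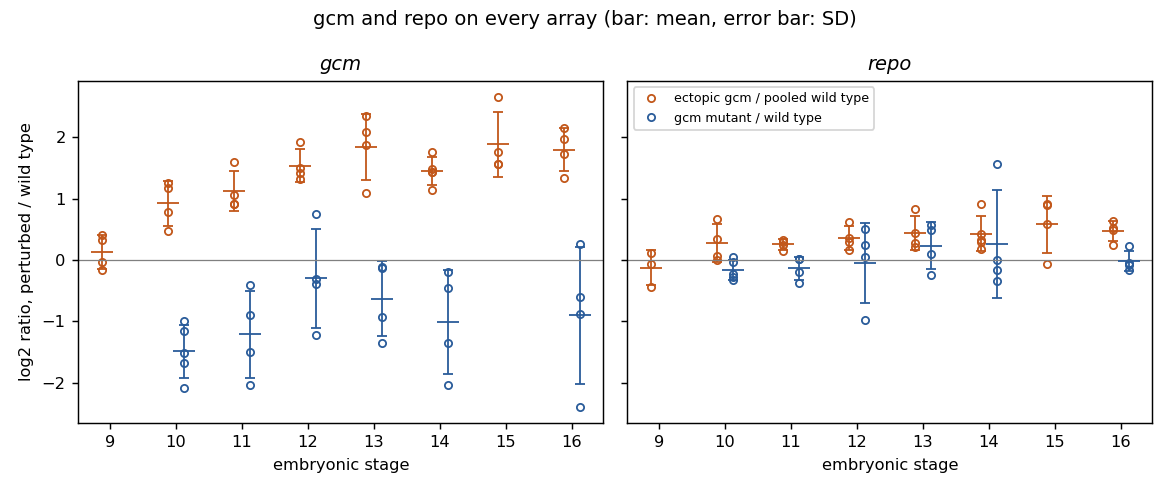
Log2 ratios of perturbed to wild-type embryos for gcm and repo on every array, by embryonic stage, for ectopic gcm and for gcm mutants. Circles are arrays, horizontal bars are group means and error bars are SDs; gcm lay above 0 on 31 of 33 gain-of-function arrays and below 0 on 23 of 25 loss-of-function arrays.

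The gain-of-function average asked which transcripts differed between embryos of the cross and the pooled wild type over stages 9 to 16. At stage 9 gcm RNA itself was not called as raised (log2 0.13, higher on 2 of 4 arrays), which does not rule out a small rise. The glial transcription factor gene repo rose 1.27-fold (log2 0.34 ± 0.07 SE, n = 32 arrays, higher on 29, adjusted p = 0.000202). The gene loco, which encodes a regulator of G-protein signalling in glia and was chosen after its values were seen, had a log2 ratio of 0.30 ± 0.06 (adjusted p = 5.53e-05). Glial genes moved apart. Of 17 measured members of the glial list, 4 rose and 8 fell, or 4 and 9 adjusted over the list alone, and the list as a whole did not pass (median log2 -0.24, adjusted p = 0.264, and adjusted p = 0.621 with an estimated correlation). The transcription factor gene retn rose by 0.69 ± 0.06 on the log2 scale, on 33 of 33 arrays, while the septate junction genes nrv2 and Nrx-IV fell by 0.59 ± 0.07 and 0.45 ± 0.08, and the innexin gene ogre fell by 0.50 ± 0.07. The loco call was lost on arrays not centred (log2 0.34), and the repo, loco and Nrx-IV calls were lost with the mean of the added maternal list as a covariate (0.31, 0.20 and -0.38), an alternative chosen after the data were seen.

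Most neuroblast genes fell in embryos with ectopic gcm. Of 19 measured neuroblast genes, 15 fell (15 also adjusted over the list alone, where 1 rose), with a median log2 ratio of -0.43. The temporal factor gene cas fell by 0.91 ± 0.10 (SE, n = 32, lower on 31 arrays), the neuroblast genes dpn and wor by 0.85 ± 0.09 and 0.73 ± 0.07, and insc, which acts in asymmetric division, by 0.71 ± 0.10. The list passed with an adjusted p of 2.84e-07, but with adjusted p = 0.0595 with an estimated correlation it did not. In the neuronal differentiation list, 5 of 15 members fell and 1 rose (5 and 2 adjusted over the list alone, median -0.14, adjusted p = 0.0761, and adjusted p = 0.244 with an estimated correlation). In it nerfin-1 fell by 0.96 ± 0.10 on 33 of 33 arrays, elav fell by 0.66 ± 0.09 and fne fell by 0.57 ± 0.10, while Csp, which encodes a synaptic vesicle chaperone, rose by 0.34 ± 0.06. The Csp call was lost with the maternal covariate (log2 0.27).

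Most members of the blood cell, tracheal, midline and Notch lists were also lower. In the blood cell list 14 of 20 members fell, 14 also adjusted over the list alone, with a median of -0.42 (adjusted p = 4.1e-05, and adjusted p = 0.0627 with an estimated correlation). The matrix genes Ppn and LanA fell by 0.57 ± 0.08 and 0.50 ± 0.07, and the receptor gene Pvr fell by 0.54 ± 0.09. In the tracheal list 6 of 7 members fell, 6 adjusted over the list alone (median -0.41, adjusted p = 0.00545, and adjusted p = 0.0595 with an estimated correlation), with uif at -0.48 ± 0.07 and rib at -0.41 ± 0.07. In the midline list 4 of 6 fell, 6 adjusted over the list alone (median -0.40, adjusted p = 0.00545, and adjusted p = 0.0595 with an estimated correlation), with -0.55 ± 0.08 for comm and -0.48 ± 0.06 for sli, both genes of axon guidance. Of 9 Notch pathway genes 5 fell, 6 adjusted over the list alone (median -0.44, adjusted p = 0.0131, and adjusted p = 0.244 with an estimated correlation), with -0.72 ± 0.10 for E(spl)mdelta-HLH and -0.63 ± 0.10 for E(spl)malpha-BFM. The rib call was lost without centring (-0.37), and with the maternal covariate the calls of Ppn (-0.36), uif (-0.32), rib (-0.33) and the midline list (-0.31) were lost.

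Among the 12 genes highest with ectopic gcm, Marf1, a regulator of oocyte meiosis, rose 4.86-fold (log2 2.28 ± 0.17 SE, n = 33, higher on 33 arrays, adjusted p = 5.7e-15). The gene smg, which encodes a repressor of maternal mRNA, rose 4.12-fold (2.04 ± 0.09, higher on 33 of 33). SoYb and tej of the piRNA pathway rose by 2.09 ± 0.16 and 2.03 ± 0.18, the embryonic linker histone gene BigH1 by 2.04 ± 0.17, and plu, needed for the first nuclear cycles, by 2.04 ± 0.18. CG18586 rose 5.96-fold, on 25 of 26 arrays, and the remaining genes were Ugt36E1 at 2.23 ± 0.19, CG5704 at 2.17 ± 0.18, Trf4-2 at 2.10 ± 0.13, CG5608 at 1.98 ± 0.20 and CG11263 at 1.93 ± 0.25. In the added maternal list, chosen after the highest genes had been seen and holding plu, 12 of 25 members rose and 1 fell, or 14 and 2 adjusted over the list alone (median 0.27, adjusted p = 5.23e-05, and adjusted p = 0.011 with an estimated correlation). Its call was lost on spot pairs (median 0.22, adjusted p = 0.0849). Among its members were tor at 1.92 ± 0.20, cact at 0.85 ± 0.08 and Tl at 0.68 ± 0.07. Of the maternal germline list fixed beforehand, 2 of 5 members rose, piwi at 1.17 ± 0.23 and aub at 1.00 ± 0.10, and 2 fell, 2 and 2 adjusted over the list alone (median 0.09, adjusted p = 0.516, and adjusted p = 0.621 with an estimated correlation). In the cell cycle list 7 of 15 members rose and 4 fell, the same counts adjusted over the list alone. Log2 ratios were 1.28 ± 0.06 for Orc1, 0.98 ± 0.10 for CycB, 0.83 ± 0.09 for CycB3 and 0.91 ± 0.09 for dup (list median 0.15, adjusted p = 0.0337, and adjusted p = 0.476 with an estimated correlation). The call of the cell cycle list was lost without replicate 1 of stage 16 (0.14) or replicate 2 of stage 9 (0.14), and its median was -0.05 with the maternal covariate. It was also lost on scaled arrays (0.16), on probes measured on every array (0.23), with array weights (0.16), on spot pairs (0.30) and on the arrays of this experiment alone (0.15). The lowest gene was CG8745 at -1.07 ± 0.12, lower on 31 of 33 arrays. Beside nerfin-1, cas and dpn, the other genes among the 12 lowest were gammaTub37C at -1.01 ± 0.19, CG2964 at -1.003 ± 0.35, the serine protease gene Jon99Ciii at -0.996 ± 0.20, and CG4467 at -0.91 ± 0.20. They also held the odorant receptor gene Or67b at -0.91 ± 0.22, CG43693 at -0.90 ± 0.12, danr at -0.84 ± 0.12 and CG8353 at -0.84 ± 0.13. The CG2964 call was lost when any 1 of 5 arrays was left out (-0.85 without replicate 3 of stage 16) and without stage 9 (-0.93), and with the maternal covariate the calls of CG2964 (-0.88), Jon99Ciii (-0.57) and CG4467 (-0.74) were lost.

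Of the remaining lists none passed in the gain-of-function average. Members that rose and fell numbered 0 and 6 of 15 neuronal identity factors (0 and 7 adjusted over the list alone), 0 and 3 of 16 muscle genes and 0 and 3 of 16 cuticle genes. They numbered 0 and 1 of 5 tendon genes (0 and 0 adjusted over the list alone), 1 and 3 of 11 fat body and gut genes and 1 and 0 of 5 apoptosis genes (1 and 1 adjusted over the list alone). Among the rest were 0 and 3 of 4 heat shock genes (0 and 4 adjusted over the list alone), 1 and 3 of 14 ecdysone genes and 0 and 1 of 35 ribosomal protein genes (0 and 0 adjusted over the list alone). The adjusted p-values of these lists ran from 0.0611 to 0.855, and from 0.244 to 0.889 with an estimated correlation. In the apoptosis list the median was -0.12, the mean 0.01 and the direction of the test lower. The ecdysone member that rose was the receptor gene EcR, at 1.03 ± 0.07. Of the 8 zygotic genes of the cellularising embryo in the second added list, limma called 0, with 1 at an unadjusted p under 0.05 (median -0.03, adjusted p = 0.5, and adjusted p = 0.583 with an estimated correlation).

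In all, limma called 4104 of 14780 tested probes in the gain-of-function average, 2090 higher and 2014 lower, of which 231 and 10 changed at least 2-fold. On arrays not centred 1854 were called, 1379 higher and 475 lower, and with the maternal covariate 1301, 797 higher and 504 lower. Averaged over stages 10 to 16, without the arrays of stage 9, 3614 of 17084 were called, 1912 higher and 1702 lower, an alternative chosen after the data were seen. Of these, 3421 were among the 4104. Spot pairs with an SD under 0.333 left 3183 probes, of which 2018 were called.

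**Figure D2:**
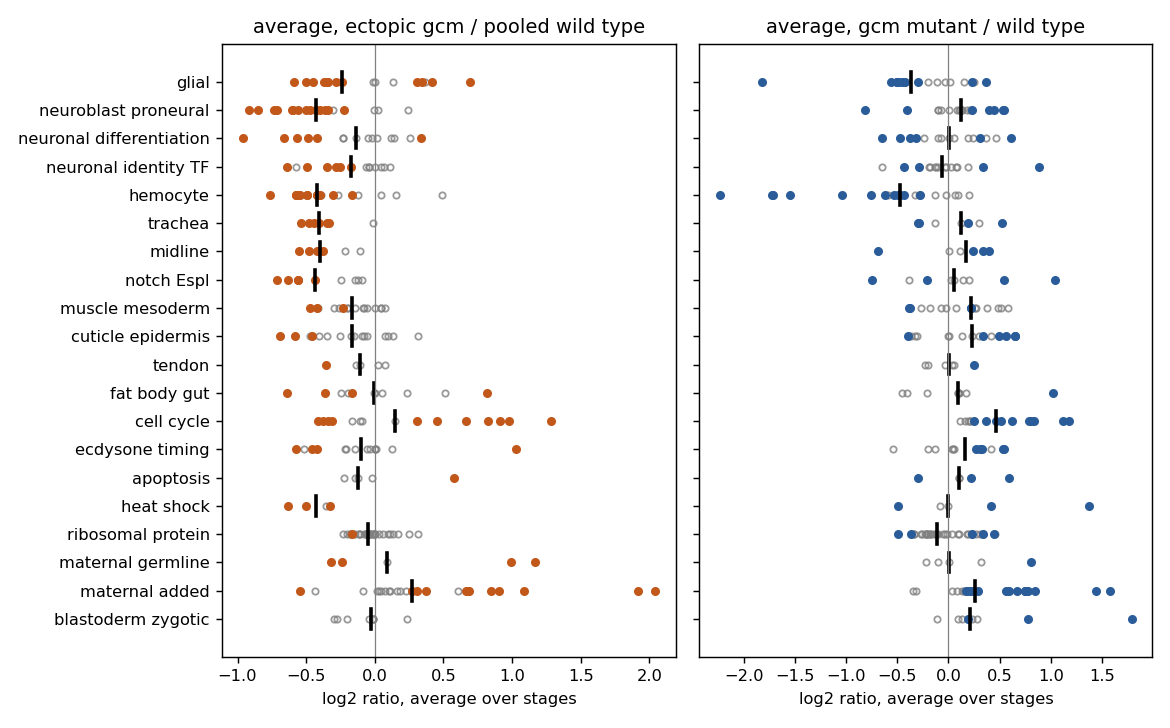
Log2 ratios of the members of each gene list, averaged over stages, for ectopic gcm over pooled wild type and for gcm mutants over wild type, with 1 probe per gene. Filled circles passed an adjusted p of 0.05, open circles did not, and vertical bars are list medians, which were -0.43 for the neuroblast list with ectopic gcm and -0.48 for the blood cell list in the mutants.

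The loss-of-function average asked the same of embryos without gcm function. Most blood cell genes fell. Of 21 measured members of the list 12 fell, 12 also adjusted over the list alone, with a median of -0.48 (adjusted p = 1.66e-08, and adjusted p = 0.0144 with an estimated correlation). PPO2, a prophenoloxidase of crystal cells, fell 4.69-fold (log2 -2.23 ± 0.15 SE, n = 25, lower on 25 arrays, adjusted p = 6.68e-16). The phagocytosis receptor gene NimC4 fell 3.3-fold (-1.72 ± 0.11, lower on 25 of 25). The matrix genes Pxn and Ppn fell by 1.71 ± 0.15 and 1.04 ± 0.09. The blood cell list did not pass on spot pairs (median -0.37, adjusted p = 0.151).

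Glial genes again moved apart in the mutants. Of 18 measured members 9 fell and 2 rose, the same adjusted over the list alone, and the list did not pass (median -0.36, adjusted p = 0.117, and adjusted p = 0.8 with an estimated correlation). The astrocyte gene alrm fell 3.53-fold (-1.82 ± 0.34 SE, n = 22, lower on 18 arrays, adjusted p = 5.46e-05). Gs2, a glutamine synthetase, fell by 0.56 ± 0.10, and Gli, Nrx-IV and nrv2 of the septate junction fell by 0.50 ± 0.09, 0.50 ± 0.09 and 0.46 ± 0.09. The log2 ratio of repo was 0.01 ± 0.08 (n = 25, higher on 12, adjusted p = 0.949), and that of loco was -0.30 ± 0.07 (adjusted p = 0.000682). Without centring the calls of loco, Gs2, Gli, Nrx-IV and nrv2 were lost (-0.15, -0.41, -0.35, -0.35 and -0.31), and with the maternal covariate those of Nrx-IV (-0.42) and nrv2 (-0.25).

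Most cell cycle genes rose in the mutants. In that list 10 of 15 members rose, 11 adjusted over the list alone (median 0.46, adjusted p = 3.1e-07, and adjusted p = 0.182 with an estimated correlation). Orc1 rose 2.27-fold (1.18 ± 0.07), CycE rose by 1.12 ± 0.16, and the mitotic cyclin genes CycB3 and CycB rose by 0.84 ± 0.11 and 0.79 ± 0.11. The vitellogenin receptor gene yl rose 10.3-fold (3.36 ± 0.19, n = 22, higher on 22 arrays, adjusted p = 3.98e-17), and Marf1 rose 6.78-fold (2.76 ± 0.19). BigH1 rose by 2.39 ± 0.19, and slam of cellularisation and swa of bicoid RNA localisation rose by 2.19 ± 0.16 and 2.03 ± 0.10, on 25 of 25 arrays each. The remaining genes among the 12 highest were Mal-A1 at 2.44 ± 0.24, Tsp42Ek at 2.19 ± 0.31, CG8607 at 2.17 ± 0.19, the potassium channel gene slo at 2.01 ± 0.26, AOX3 at 1.97 ± 0.22, CG46385 at 1.94 ± 0.07 and CG17839 at 1.93 ± 0.32. In the added maternal list 13 of 23 members rose (median 0.26, adjusted p = 3.66e-05, and adjusted p = 0.0142 with an estimated correlation), among them gnu at 1.579 ± 0.24, plu at 1.44 ± 0.22, wisp at 0.56 ± 0.07 and grk at 0.59 ± 0.10. In the list of zygotic genes of the cellularising embryo 3 of 8 rose, among them halo at 1.79 ± 0.34 and bnk at 0.77 ± 0.17 (median 0.21, adjusted p = 0.0477, and adjusted p = 0.107 with an estimated correlation). The list's call was lost when any 1 of 12 arrays was left out, with the highest p, 0.132, without replicate 2 of stage 14 (median 0.18). It was lost as well on probes measured on every array (0.16), with array weights (0.11), with values of 5 or more left out (0.18) on the arrays of this experiment alone (0.21) and in the fit without gain-of-function stage 9 (adjusted p = 0.052). With the maternal covariate the calls of CycB (0.44), CycE (0.74), halo (1.587), bnk (0.40) and CG17839 (1.39) were lost. Those of plu (0.20) and gnu (0.96) were lost there too, but both belong to the list behind the covariate, so this does not test them. On spot pairs the calls of the cell cycle list (0.22) and the added maternal list (0.16) were lost.

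Among the genes lowest in the mutants were CG7763 at -2.34 ± 0.11, the pteridine synthesis gene pr at -2.22 ± 0.15, CG14973 at -2.01 ± 0.23 and the peroxiredoxin gene Prx6b at -1.99 ± 0.13. Beside these and PPO2, NimC4, Pxn and alrm, the 12 lowest held CG12896 at -1.86 ± 0.14, NtR at -1.68 ± 0.16, Sirup at -1.64 ± 0.27 and CG8112 at -1.62 ± 0.14. In the neuroblast list 5 of 18 members rose and 2 fell, the same adjusted over the list alone (median 0.12, adjusted p = 0.384, and adjusted p = 0.863 with an estimated correlation). The temporal factor genes Kr and hb rose by 0.54 ± 0.10 and 0.44 ± 0.08 and cas fell by 0.82 ± 0.11. In the Notch list 2 of 9 rose and 2 fell, 3 and 2 adjusted over the list alone, with 1.04 ± 0.11 for the ligand gene Delta (median 0.06, adjusted p = 0.748, and adjusted p = 0.863 with an estimated correlation). Of the cuticle list 5 of 15 rose and 1 fell, 6 and 1 adjusted over the list alone, with 0.65 ± 0.09 for Ccp84Ab (adjusted p = 0.195, and adjusted p = 0.769 with an estimated correlation). Of the maternal germline list 1 of 5 rose, piwi at 0.80 ± 0.27 (list adjusted p = 0.748, and adjusted p = 0.863 with an estimated correlation), a call lost without replicate 1 of stage 11 (0.66), replicate 1 of stage 16 (0.65) or replicate 4 of stage 13 (0.64). It was lost too with no dye term (adjusted p = 0.0798), on the arrays of this experiment alone (0.1), with zeros kept (0.21), with values of 5 or more left out (0.0543) and with the maternal covariate (0.118). In the ecdysone list 5 of 12 rose, with 0.53 ± 0.08 for EcR (list adjusted p = 0.195, and adjusted p = 0.737 with an estimated correlation). The lists of neuronal differentiation, neuronal identity, tendon, muscle, trachea, midline, fat body and gut, apoptosis, heat shock and ribosomal proteins had adjusted p-values from 0.632 to 0.748, and from 0.863 to 0.884 with an estimated correlation. They had 2 and 4 of 15, 2 and 2 of 16, 1 and 0 of 6, 2 and 2 of 15, 2 and 2 of 7, 3 and 1 of 6, 1 and 0 of 9, 2 and 1 of 5, 2 and 1 of 5, and 3 and 2 of 34 members higher and lower, in that order. Adjusted over the list alone, the counts changed only for muscle (3 and 2) and ribosomal proteins (2 and 2). Median, mean and test differed in sign for the neuronal differentiation list (0.00516, 0.000304 and lower), the tendon list (0.00343, -0.0187 and higher) and the heat shock list (-0.000162, 0.242 and higher).

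In all, limma called 4153 of 15025 tested probes in the loss-of-function average, 2087 higher and 2066 lower, of which 227 and 140 changed at least 2-fold. On arrays not centred, which moved the median of all tested probes from 0.00147 to 0.16, 2105 were called, 1634 higher and 471 lower. With the maternal covariate 1606 were called, 708 higher and 898 lower, and spot pairs with an SD under 0.333 left 2116 probes, of which 1486 were called.

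At single stages, Ugt36E1, a UDP-glycosyltransferase gene, was among the highest with ectopic gcm at stage 10 (log2 3.83 ± 0.52 SE, n = 4). In the mutants CG14973 was among the lowest at stage 10 (-4.23 ± 0.50, n = 5), yl among the highest at stage 11 (4.13 ± 0.52, n = 3) and alrm among the lowest at stage 16 (-4.06 ± 0.80, n = 4). Marf1 was among the highest at stage 10 (3.63 ± 0.43, n = 5) and halo at stage 13 (4.61 ± 0.81, n = 4). Among the lowest were fok and CG14973 at stage 11 (-3.55 ± 0.39 and -4.02 ± 0.57, n = 4) and CG6902 at stage 13 (-5.62 ± 0.74, n = 4). With ectopic gcm, CG5084 was among the lowest at stage 9 (-3.34 ± 0.86, n = 3), and the chitin synthase gene kkv at stage 11 (-2.49 ± 0.52, n = 4). So were Vps36 at stage 15 (-1.50 ± 0.30, n = 4) and lds at stage 16 (-2.16 ± 0.40, n = 4). These calls were lost without replicate 4 for CG5084 (-3.12) and lds (-1.19), without replicate 2 or 3 for kkv (-1.82 and -1.74) and without replicate 2 for Vps36 (-0.95). Those of kkv (-2.37), Vps36 (-1.18) and lds (-2.22) were lost on arrays not centred. With a replicate block the calls of Vps36 (-1.425) and of alrm at loss-of-function stage 16 (-3.845) were lost. With values of 5 or more left out lds was lost (-1.09), as it was with the maternal covariate (-1.80), and CG5084 was lost with zeros kept (-1.75). With the spread shared across all 58 arrays, limma called 1663, 1012, 662, 438, 713, 322, 110 and 51 probes at gain-of-function stages 9 to 16 and 1272, 1650, 1490, 2060, 570 and 779 at loss-of-function stages 10 to 14 and 16. With ectopic gcm stage 9, where gcm was not called, had the most. Stage 10 had more without centring or arrays lacking over 40%, on scaled arrays, on spot pairs and with array weights. From the arrays of a stage alone, limma called 0 at each of the 14 stages, with 1028 to 3462 probes at an unadjusted p under 0.05. Single arrays moved these counts by over 1.5 times. The gain-of-function count became 472 at stage 9 without replicate 1, 280 and 421 at stage 10 without replicates 1 and 4, 412, 267 and 286 at stage 11 without replicates 2, 3 and 4, and 201, 239, 283 and 192 at stage 12 without replicates 1, 2, 3 and 4. It became 338 and 348 at stage 13 without replicates 2 and 3 and 187 and 214 at stage 14 without replicates 2 and 3. For the last stages it was 70, 24, 61 and 33 at stage 15 without replicates 1, 2, 3 and 4, and 23, 29 and 30 at stage 16 without replicates 1, 3 and 4. The loss-of-function count became 728 at stage 12 without replicate 3, 1228 and 1229 at stage 13 without replicates 1 and 3, 226, 273 and 165 at stage 14 without replicates 1, 2 and 4, and 359 at stage 16 without replicate 2. At least 1 stage called 2665 probes with ectopic gcm and 4952 in the mutants, and at least 3 stages called 550 and 639.

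The next question was whether the response changed with stage. With ectopic gcm, the log2 ratio of gcm itself was higher by 0.81 ± 0.20 (SE, n = 33, adjusted p = 0.0264) at stages 13 to 16 than at stages 9 to 12, and that of Nagk, an N-acetylglucosamine kinase gene, by 1.00 ± 0.20. The glial list had a median difference of 0.34, with 2 of 17 members passing and 5 adjusted over the list alone (adjusted p = 9.66e-06, and adjusted p = 0.068 with an estimated correlation), namely htl at 0.73 ± 0.16 and moody at 0.73 ± 0.19. In the blood cell list the median difference was 0.39, and NimC4 at 0.81 ± 0.18 was the 1 of 20 members that passed, or 9 adjusted over the list alone (adjusted p = 1.59e-06, and adjusted p = 0.068 with an estimated correlation). AP-2alpha was higher late by 0.90 ± 0.20, while CG30440 fell by 1.93 ± 0.24 and BicD of the added maternal list by 1.09 ± 0.24. The other genes of the rule were CG13280 (1.65 ± 0.44), Septin5 (0.98 ± 0.25), Spn42Dc (0.93 ± 0.25), Cpr67Fa1 (-2.12 ± 0.54), EAChm (-1.83 ± 0.47), GstE11 (-1.66 ± 0.39), CG3842 (-1.65 ± 0.28) and, from the cell cycle list, CycB (0.75 ± 0.20). For repo the difference was 0.29 ± 0.14 (adjusted p = 0.389, though it passed on spot pairs, at 0.33) and for gcm2 0.10 ± 0.38 (adjusted p = 0.953). The added maternal list as a whole had a median of -0.18 (adjusted p = 0.00386, and adjusted p = 0.0813 with an estimated correlation).

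Of 14780 probes, limma called 201 as different between late and early gain-of-function stages, 44 higher late and 157 lower. That count became 130 without replicate 1 of stage 9, 128 without replicate 4 of stage 10, 132 and 126 without replicates 3 and 4 of stage 11 and 121 without replicate 3 of stage 15. Only 1 probe was called without centring (0 higher, 1 lower, 722 at an unadjusted p under 0.05), so that of the genes named only CG30440 passed, and arrays scaled to one spread gave 434, 164 higher and 270 lower. The gcm call was lost without replicate 3 or 4 of stage 11 (0.78 and 0.78) or replicate 3 of stage 15 (0.75), and with any 1 of 21 arrays left out the moody call was lost (range over all arrays 0.61 to 0.79). The same held for CycB with 18 arrays (0.68 to 0.83), CG13280 with 22 (1.45 to 1.85), Spn42Dc with 21 (0.79 to 1.07), Cpr67Fa1 with 17 (-2.55 to -1.77), EAChm with 10 (-2.05 to -1.55) and Septin5 with 5 (0.86 to 1.07). With zeros kept the calls of gcm (adjusted p = 0.097), htl (0.0812), moody (0.186), NimC4 (0.0701), Septin5 (0.0701), Spn42Dc (0.21), CycB (0.105) and Cpr67Fa1 (0.142) were lost. So were those of CG13280 (adjusted p = 0.261) and EAChm (0.129), whose log2 differences became 0.9994 and -1.09. Without arrays lacking over 40% those of gcm (adjusted p = 0.0675), moody (0.131), Septin5 (0.0891), Spn42Dc (0.0964), CycB (0.093), CG13280 (0.0661) and Cpr67Fa1 (0.0833) were lost. With the maternal covariate gcm (adjusted p = 0.0589), htl (0.0594), moody (0.206), AP-2alpha (0.0711), GstE11 (0.0915), Septin5 (0.0625), Spn42Dc (0.166) and Cpr67Fa1 (0.0987) no longer passed. Their differences there were 0.86 ± 0.22, 0.68 ± 0.17, 0.63 ± 0.21, 0.80 ± 0.21, -1.55 ± 0.42, 1.05 ± 0.27, 0.87 ± 0.27 and -2.28 ± 0.62 (SE) in that order, each within 1 SE of the value without the covariate and with a larger SE. Nor did BicD (adjusted p = 0.124) or the added maternal list (0.163), which the covariate does not test because it holds them. With no filter on missing values moody (adjusted p = 0.064), Spn42Dc (0.0669), CycB (0.0567), CG13280 (0.068) and Cpr67Fa1 (0.0567) did not pass. With no dye term CycB (adjusted p = 0.096), CG13280 (0.0686) and Cpr67Fa1 (0.0598) did not. On the arrays of this experiment alone the calls of CG13280 (adjusted p = 0.064), Spn42Dc (0.0806) and EAChm (0.0702) were lost. Spn42Dc did not pass with array weights either (0.51), nor moody with values of 5 or more left out (0.59). Without stage 9, where gcm was not called, 108 probes were called, 10 higher late and 98 lower. The calls of gcm (0.54), Nagk (0.78), htl (0.49), moody (0.74), NimC4 (0.70), CycB (0.68), CG13280 (1.39), Septin5 (0.85), Spn42Dc (0.90), Cpr67Fa1 (-1.79) and EAChm (-1.94) were then lost.

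In the mutants, genes of the cuticle had higher ratios at stages 13, 14 and 16 than at stages 10 to 12. In the list 5 of 15 members passed, 6 adjusted over the list alone, with a median of 0.48 (adjusted p = 8.65e-06, and adjusted p = 0.00616 with an estimated correlation). Ccp84Ab and Ccp84Aa were higher late by 1.595 ± 0.18 and 1.601 ± 0.24, TwdlM by 2.41 ± 0.50, and TwdlK, a gene of the same family as TwdlM, by 3.09 ± 0.55 (adjusted p = 0.000207). CG14973 was higher late by 3.05 ± 0.45, Inos, an inositol phosphate synthase gene, by 2.88 ± 0.34, and SNCF by 2.59 ± 0.52. Also higher late were nerfin-1 at 1.29 ± 0.24, elav at 0.80 ± 0.20, wor at 0.66 ± 0.15, E(spl)mdelta-HLH at 1.29 ± 0.22, Gs2 at 1.51 ± 0.19 and the chromosomal passenger gene Incenp at 1.02 ± 0.18. Of 15 neuronal differentiation genes 2 passed, 4 adjusted over the list alone (median 0.35, adjusted p = 0.0238, and adjusted p = 0.194 with an estimated correlation). Of 18 neuroblast genes 6 were higher, and 6 higher and 1 lower adjusted over the list alone (median 0.26, adjusted p = 0.0238, and adjusted p = 0.482 with an estimated correlation). The first list did not pass on arrays not centred (0.93), on probes measured on every array (0.38) or with array weights (0.46). The second did not pass on probes measured on every array (0.21) or on spot pairs (0.11). In contrast alrm fell by 2.77 ± 0.68 and PPO1 fell by 1.53 ± 0.33. The other genes of the rule were CG5404 (2.65 ± 0.56), vvl of the tracheal list (0.54 ± 0.14), CG14151 (-3.03 ± 0.90), Ir7g (-2.64 ± 0.68), Ir7c (-2.48 ± 0.76) and Cyp6v1 (-2.32 ± 0.47). The difference was 0.13 ± 0.23 for gcm (n = 25, adjusted p = 0.827), -1.18 ± 0.43 for gcm2 (adjusted p = 0.104, and -1.07 with values of 5 or more left out, where it passed) and 0.27 ± 0.16 for repo (adjusted p = 0.385).

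Of 15025 probes, limma called 836 between late and early loss-of-function stages, 595 higher late and 241 lower. On arrays not centred, which moved the median of all tested probes from 0.06 to 0.64, 2654 were called, 2628 higher and 26 lower, and the calls of PPO1 (-0.95), CG14151 (-2.28) and Ir7c (-1.91) were lost, while repo passed (0.85). The arrays of this experiment alone gave 304, 200 higher and 104 lower, without a call for wor, vvl, CG14151, Ir7g or Ir7c. With any 1 of 9 arrays left out the CG14151 call was lost (-3.29 to -2.57), with any 1 of 12 the Ir7c call (-2.90 to -1.99), and without replicate 4 of stage 16 the Ir7g call (-2.08), which was lost too with values of 5 or more left out (-1.81), while gcm2 passed without replicate 3 of stage 10 (-1.43). The calls of CG14151 and Ir7c were lost on scaled arrays (adjusted p = 0.125 and 0.059), with no filter on missing values (0.0582 and 0.0606) and with array weights (0.0964 and 0.1). They were lost as well without arrays lacking over 40% (adjusted p = 0.0594 and 0.0846) and with the maternal covariate (0.0929 and 0.0541), and that of Ir7c with no dye term (0.0591). The sorting marker changed between stages 13 and 14, so late minus early cannot fully separate stage from marker.

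The last question was which genes moved in opposite directions with gain and loss of gcm. The difference of gain minus loss over the 6 shared stages was 2.41 ± 0.16 for gcm itself (n = 50 arrays). Nagk rose with ectopic gcm (0.81 ± 0.10, higher on 30 of 33 arrays) and fell in the mutants (-1.55 ± 0.12, lower on 25 of 25). So did CG6180 (0.62 ± 0.12 and -0.97 ± 0.14) and CG31674 (0.96 ± 0.22 and -1.03 ± 0.25). The same direction held for CG7668 (0.62 ± 0.14 and -0.80 ± 0.16), CG2767 (0.62 ± 0.10 and -0.60 ± 0.11), GAPsec (0.60 ± 0.11 and -0.66 ± 0.13) and CG17883 (0.56 ± 0.10 and -0.79 ± 0.11). The opposite held for zpg, an innexin gene of the germ line (-0.67 ± 0.15 and 1.57 ± 0.17), for Kr (-0.56 ± 0.08 and 0.54 ± 0.10), for dan (-0.68 ± 0.09 and 0.53 ± 0.11) and CG43693 (-0.90 ± 0.12 and 0.87 ± 0.14). It held too for Vajk4 (-0.69 ± 0.21 and 0.66 ± 0.23), gammaTub37C (-1.01 ± 0.19 and 0.63 ± 0.22), the helicase gene Blm (-0.61 ± 0.19 and 1.25 ± 0.21) and the heat shock gene Hsp70Bb (-0.54 ± 0.17 and 0.71 ± 0.20). The difference was 2.44 ± 0.17 for Nagk, 1.583 ± 0.20 for CG6180, 2.09 ± 0.35 for CG31674, -2.33 ± 0.24 for zpg and -1.03 ± 0.14 for Kr. It was 1.33 ± 0.23 for CG7668, 1.22 ± 0.16 for CG2767, 1.23 ± 0.18 for GAPsec, 1.25 ± 0.16 for CG17883 and -1.17 ± 0.15 for dan. The remaining differences were -1.76 ± 0.20 for CG43693, -1.34 ± 0.33 for Vajk4, -1.577 ± 0.32 for gammaTub37C, -1.88 ± 0.30 for Blm and -1.23 ± 0.28 for Hsp70Bb, and 0.49 ± 0.31 for gcm2 (adjusted p = 0.306, though it passed with array weights, at 0.80). For repo it was 0.37 ± 0.12 (adjusted p = 0.0171), a call lost on arrays not centred (0.26) and with zeros kept (0.34). Several calls of an average behind these opposite changes were unstable. Without centring, those of CG2767 (-0.45) and GAPsec (-0.51) in the mutants and of Vajk4 (-0.66), Blm (-0.53) and Hsp70Bb (-0.51) with ectopic gcm were lost. In the mutants the Vajk4 call was lost with any 1 of 7 arrays left out (0.58 to 0.75 over all arrays) and the gammaTub37C call with any 1 of 8 (0.49 to 0.83). The Vajk4 call there was also lost on scaled arrays (adjusted p = 0.0537), with array weights (0.144) and without arrays lacking over 40% (0.067). That of gammaTub37C was lost with no dye term (adjusted p = 0.0748), on the loss-of-function arrays alone (0.152) and without arrays lacking over 40% (0.0742). With the maternal covariate gammaTub37C was -0.18 in the mutants, the reverse of its direction, and the calls of CG7668 (0.46), GAPsec (0.29), CG17883 (0.44), Vajk4 (-0.49), Blm (-0.84) and Hsp70Bb (-0.69) with ectopic gcm and of CG2767 (-0.52), Vajk4 (0.90), Blm (0.97) and Hsp70Bb (0.54) in the mutants were lost. Neuroblast genes were lower in the gain than in the loss, in 10 of 18 members and 14 adjusted over the list alone (median -0.48, adjusted p = 2.04e-09, and adjusted p = 0.0228 with an estimated correlation). Midline genes were lower in 4 of 6 members and 5 adjusted over the list alone (-0.48, adjusted p = 0.00166, and adjusted p = 0.0228 with an estimated correlation).

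Most shared changes had the same direction. Over the 12223 probes tested in both averages, 780 were higher in both against 329.7 for independent lists (Fisher's exact test, p = 2.97e-161) and 867 lower in both against 318.8 (p = 8.61e-238). Opposite changes were fewer than for independent lists, with 201 higher in the gain and lower in the loss against 329 (Fisher's exact test, p = 8.89e-19) and 195 the reverse against 319.4 (p = 2.86e-18). Probes are not independent replicates. The averages correlated across probes with r = 0.34 and rho = 0.299. The difference between the experiments was called for 2308 of 13264 probes, 1453 higher and 855 lower in the gain. On arrays not centred, which moved the median of all tested probes from 0.02 to -0.10, 464 were called, 132 higher and 332 lower. Changes shared in the same direction then fell from 1647 to 612 and opposite changes from 396 to 69. With the maternal covariate they numbered 311 and 35, and on spot pairs, with fewer probes tested, 494 and 187. With the covariate the CG31674 call in the mutants was lost (-0.22).

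**Figure D3:**
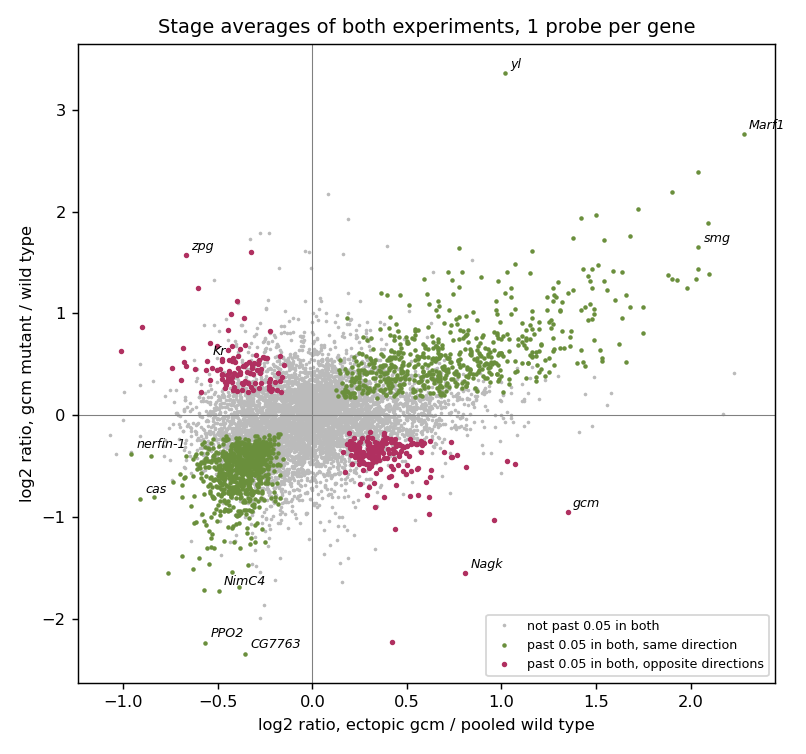
Average log2 ratios of gcm mutants over wild type (vertical axis) against those of ectopic gcm over pooled wild type (horizontal axis), 1 probe per gene. Grey points did not pass an adjusted p of 0.05 in both experiments, green points passed in the same direction and magenta points in opposite directions; of genes, 621 were higher in both and 733 lower in both, against 170 and 105 in opposite directions.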

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

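The tests of egg, cellularising and diluting RNA were written after the results they address had been seen, and those of the neighbours of gcm and of other splits of the arrays before.

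Single arrays stood apart from the others of their stage in 5 of 110 tests, and chance gives about 1 in 20. For loco these were replicate 3 of gain-of-function stage 15 (0.7985, others 0.217 to 0.3135), replicate 1 of loss-of-function stage 14 (-0.896, others 0.1175 to 0.1615) and replicate 2 of loss-of-function stage 11 (-1.118, others -0.366 to -0.2165). The mean of the glial list stood apart on replicate 1 of loss-of-function stage 10 (-0.7987, others -0.3749 to -0.3608). The mean of the blood cell list did so on replicate 3 of gain-of-function stage 9 (-1.019, others -0.5817 to -0.5213).

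Late and early stages differed at 201 probes with ectopic gcm and at 836 in the mutants, and gain and loss of function at 2308 probes, each by a test of the difference. gcm 0.81, Nagk 1.004, AP-2alpha 0.90, CG30440 -1.93, htl 0.73, moody 0.73, NimC4 0.81, BicD -1.09, CG3842 -1.65 and GstE11 -1.66 were log2 differences of late minus early stages with ectopic gcm. CycB 0.75, CG13280 1.65, Septin5 0.98, Spn42Dc 0.93, Cpr67Fa1 -2.12 and EAChm -1.83 were further differences there. TwdlK 3.09, CG14973 3.05, Inos 2.88, SNCF 2.59, alrm -2.77, Ccp84Ab 1.595, Ccp84Aa 1.601, TwdlM 2.41, nerfin-1 1.29 and elav 0.80 were such differences in the mutants, where the sorting marker changed within the late stages. Gs2 1.51, PPO1 -1.53, Incenp 1.02, E(spl)mdelta-HLH 1.29, wor 0.66, CG14151 -3.03, Ir7g -2.64, Cyp6v1 -2.32, CG5404 2.65 and vvl 0.54 also differed in the mutants. Ir7c -2.48 differed as well. gcm 2.41, Nagk 2.44, CG31674 2.09, CG6180 1.583, zpg -2.33, Kr -1.03, repo 0.37, dan -1.17, CG43693 -1.76 and CG7668 1.33 were differences of gain minus loss, whose wild types were not the same. CG2767 1.22, GAPsec 1.23, CG17883 1.25, Vajk4 -1.34, gammaTub37C -1.577, Blm -1.88 and Hsp70Bb -1.23 differed between the experiments too. List medians that differed late minus early were glial 0.34, blood cell 0.39, midline 0.33, cell cycle 0.18 and Notch 0.26 with ectopic gcm, and none held with an estimated correlation (adjusted p = 0.068, 0.068, 0.068, 0.631 and 0.416). Without stage 9 the midline (0.18), cell cycle (0.0657) and Notch (0.19) calls were lost. In the mutants they were neuronal differentiation 0.35, neuroblast 0.26, cuticle 0.48, trachea 0.35, cell cycle 0.54 and Notch 0.38, of which only cuticle held with an estimated correlation (adjusted p = 0.194, 0.482, 0.00616, 0.224, 0.235 and 0.235). on spot pairs the neuroblast, cell cycle and Notch calls in the mutants were lost (adjusted p = 0.876, 0.0576 and 0.0576). Gain minus loss they were neuroblast -0.48, cuticle -0.28, trachea -0.44, midline -0.48, cell cycle -0.46 and Notch -0.70, of which neuroblast and midline held with an estimated correlation (adjusted p = 0.0228, 0.195, 0.0623, 0.0228, 0.389 and 0.158).

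Calls of several of these lists depended on single arrays. With ectopic gcm the late minus early call of the cell cycle list was lost with any 1 of 11 arrays left out (0.12 to 0.22 over all arrays). That of the Notch list was lost with any 1 of 4 (0.21 to 0.32). In the mutants the neuronal differentiation and tracheal calls were lost with any 1 of 3 arrays left out (0.25 to 0.41 and 0.31 to 0.53) and the neuroblast call with 1 (0.17 to 0.32). In limma 0 of 6 midline and 0 of 9 Notch genes passed late minus early with ectopic gcm, with 2 and 2 at an unadjusted p under 0.05.

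Members of the added maternal list, chosen after the highest genes were seen, were higher in both experiments, which egg or very early embryo RNA in the perturbed samples could give. The maternal germline list fixed beforehand passed in neither (adjusted p = 0.516 and 0.748) and had a median of 0.0891 with ectopic gcm (spread 0.624, 0.135 needed) and of 0.00335 in the mutants (spread 0.368, 0.128 needed), so neither test can tell. Genes of the cellularising embryo had a median of -0.0278 with ectopic gcm (spread 0.125), which shows no rise but cannot exclude a few such embryos. In the mutants the median was 0.213 (spread 0.429), which cannot tell. Delayed clearance of maternal RNA in perturbed embryos was not tested and may give the same pattern.

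Blood cell genes were lower in the mutants, and dilution of embryo RNA by other RNA would lower all zygotic tissues alike. The blood cell median lay 0.606 below that of the muscle, neuronal differentiation, cuticle and tracheal lists pooled (-0.475 against 0.131 over 52 members). The permutation p of 1e-05, the smallest possible, treats genes as independent. The gap argues against dilution alone, though the glial list (-0.36) was not in the pool. Blood cell genes were lower with ectopic gcm as well, a call that did not hold with an estimated correlation (adjusted p = 0.0627). Gain minus loss of the blood cell list had a median of 0.192 (p = 0.248 with an estimated correlation). For the list as a whole an effect of the loss beyond what both experiments share could therefore not be told. Of its 20 members 6 were lower in the loss than in the gain, PPO2, NimC4, Pxn, PPO1, crq and Ppn, and LanA was the reverse. These tests, which did not separate blood cell types, leave a role of gcm in blood cells open.

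Sequence linked to the mutant gcm locus could also change nearby genes. Among the genes around gcm, 20 of 42 (47.6%) passed in the mutants against 33.5% of other genes (odds ratio 1.8, 95% interval 0.931 to 3.47, p = 0.0703 by Fisher's exact test). With ectopic gcm 17 of 41 (41.5%) passed against 36.1% (odds ratio 1.25, interval 0.631 to 2.44, p = 0.516 by Fisher's exact test). Neither can tell linked sequence from none.

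Other splits of the arrays gave fewer calls for most results. The real split was 1 of 100 to reach its count for the gain-of-function average (4104, highest other 338), the loss-of-function average (4153, highest other 991) and the opposite changes (396, highest other 2). The same held for late minus early with ectopic gcm (201, highest other 1) and gain minus loss (2308, highest other 21). Late minus early in the mutants was reached by 2 of 100 splits, the real one with 836 and another with 1008. Splits within a stage, 3 to 10, are too few for a share under 0.05. There the highest other counts were 20, 2, 1, 0, 15, 11, 4 and 0 at gain-of-function stages 9 to 16. In the mutants they were 175, 128, 23, 56, 2 and 5.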

How the results depend on the processing

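Of the alternatives, zeros kept, log2 values of 5 or more left out, print blocks centred, arrays lacking over 40% left out, the maternal covariate and gain-of-function stage 9 left out were chosen after the data were seen. All 20 counts stayed within 1.5 times their value with no dye term, no filter on missing values, a robust prior, probes measured on every array, print blocks centred and values of 5 or more left out. The cause of a change below was not tested unless a cause is named. No intensities were given, so signal over background could not be tied to any change.

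Direction and side of the threshold were kept by 204 of 248 gene results and 19 of 23 list results without centring. Scaling kept 239 of 248 gene and 20 of 23 list results. The fit without a dye term kept 240 of 248 and 23 of 23, and array weights 236 of 248 and 18 of 23. With probes measured on every array 185 of 186 gene and 16 of 23 list results were kept. Without a filter 240 of 248 and 23 of 23 were kept, and with a robust prior 248 of 248 and 23 of 23. Spot pairs under the SD limit kept 63 of 71 gene and 7 of 16 list results. The gain-of-function arrays alone kept 112 of 116 and 12 of 13, and the loss-of-function arrays alone 102 of 114 and 8 of 10. Of the added alternatives, zeros kept left 232 of 248 gene and 23 of 23 list results as they were. Values of 5 or more left out kept 229 of 237 and 20 of 23, and print blocks centred 247 of 248 and 23 of 23. Leaving out arrays lacking over 40% kept 232 of 244 gene and 21 of 23 list results. The maternal covariate kept 200 of 248 and 19 of 23. Leaving out gain-of-function stage 9 kept 231 of 244 gene results and 19 of 23 list results.

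Without centring, limma called 65, 230, 68, 77, 22, 9, 26 and 0 at gain-of-function stages 9 to 16 (with 786 at stage 16 at an unadjusted p under 0.05). In the mutants it called 313, 764, 77, 1025, 224 and 399 at loss-of-function stages 10 to 14 and 16. The other counts without centring were 1854 for the gain-of-function average, 2105 for the loss-of-function average, 1 for gain-of-function late minus early, 2654 for loss-of-function late minus early, 464 for gain minus loss and 69 for the opposite changes. Median log2 ratios of all tested probes without centring lay between -0.38 and 0.46 at single stages. Scaled arrays gave 1934, 1276, 1132, 1324, 684 and 489 at gain-of-function stages 10, 11, 12, 14, 15 and 16. They gave 962, 761 and 1059 at loss-of-function stages 11, 12 and 13 and 434 for gain-of-function late minus early. Array weights gave 3129, 3251, 3017, 1701, 1088, 2765 and 1547 at gain-of-function stages 10 to 16. In addition they gave 3119 and 2608 at loss-of-function stages 10 and 12, 1050 for gain-of-function late minus early, 3599 for gain minus loss and 650 for the opposite changes. Spot pairs under the SD limit, which left fewer probes to test, gave 3005, 2514, 1490, 1673, 1159, 703 and 504 at gain-of-function stages 10 to 16. For the mutants they gave 2204, 2561, 1924 and 1283 at loss-of-function stages 10, 12, 14 and 16. The other counts from spot pairs were 2018 for the gain-of-function average, 1486 for the loss-of-function average, 669 for gain-of-function late minus early, 398 for loss-of-function late minus early, 966 for gain minus loss and 187 for the opposite changes. The gain-of-function arrays alone gave 1559, 1123, 703, 1162, 568, 323 and 148 at gain-of-function stages 10 to 16. Late minus early they gave 401. The loss-of-function arrays alone gave 673, 867, 324, 837, 85 and 330 at loss-of-function stages 10 to 14 and 16. Late minus early they gave 304. From the arrays of 1 stage alone limma called 0 at each stage. At an unadjusted p under 0.05 there were 2635, 3259, 3462, 2514, 1654, 1969, 1925 and 1695 at gain-of-function stages 9 to 16. At loss-of-function stages 10 to 14 and 16 there were 3289, 1028, 2279, 1841, 2369 and 2307. Zeros kept gave 935 and 29 at gain-of-function stages 9 and 16, 880 at loss-of-function stage 12 and 67 for gain-of-function late minus early. Without arrays lacking over 40% there were 483 and 202 at gain-of-function stages 9 and 14 and 113 for gain-of-function late minus early. With the maternal covariate there were 820, 226, 152, 46, 346, 145, 73 and 13 at gain-of-function stages 9 to 16. In the mutants there were 613, 643 and 513 at loss-of-function stages 10, 12 and 13. Its other counts were 1301 for the gain-of-function average, 1606 for the loss-of-function average, 71 for gain-of-function late minus early and 35 for the opposite changes. Without gain-of-function stage 9 there were 108 for gain-of-function late minus early.

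Replicate numbers pair no arrays in the design. Residuals of arrays with the same number correlated across probes with a median r of -0.04 in both experiments, over 0.1 in 2 of 112 and 2 of 60 pairs, and 5 of 33 and 0 of 25 arrays correlated best with one of their own number. A replicate block gave 1050, 646, 429, 442, 37 and 20 at gain-of-function stages 9, 10, 11, 13, 15 and 16 and 810, 988, 270 and 238 at loss-of-function stages 11, 12, 14 and 16. It gave 2145 for the gain-of-function average, 1879 for the loss-of-function average, 771 for gain minus loss, 72 for the opposite changes and 541 for those in the same direction. Of the gene and list results, 211 of 246 and 19 of 23 kept their call.

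Leaving out 1 array at a time, counts ranged over 472 to 1510, 280 to 854, 267 to 519, 192 to 283, 338 to 750, 187 to 295, 24 to 70 and 23 to 38 at gain-of-function stages 9 to 16. They ranged over 915 to 1123, 1118 to 2061, 728 to 1200, 1228 to 2273, 165 to 726 and 359 to 668 at loss-of-function stages 10 to 14 and 16. The other ranges were 3640 to 4152 for the gain-of-function average, 3891 to 4358 for the loss-of-function average, 121 to 242 for gain-of-function late minus early, 703 to 1083 for loss-of-function late minus early, 2143 to 2539 for gain minus loss and 358 to 462 for the opposite changes.

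Values not turned for the dye mix both orientations, which by construction sets opposite signs against each other. Limma then called 36, 12, 0, 5, 5, 20, 2 and 0 at gain-of-function stages 9 to 16 (973 and 863 at an unadjusted p under 0.05 at stages 11 and 16). For the mutants it called 74, 90, 170, 64, 46 and 42 at loss-of-function stages 10 to 14 and 16. The other counts were 219 for the gain-of-function average, 513 for the loss-of-function average, 0 for gain-of-function late minus early, 0 for loss-of-function late minus early, 48 for gain minus loss and 0 for the opposite changes, with 317 and 858 late minus early at an unadjusted p under 0.05. Not turned, 106 gene and 14 list results reversed. nrv2 0.0630, ogre 0.25, Nrx-IV 0.0753, CG18586 -0.0561, Marf1 -0.0583, SoYb -0.34, plu -0.0798, tej -0.18 and CG8745 0.11 were gain-of-function averages. wor 0.0275, insc 0.14, elav 0.24, Ppn 0.11, LanA 0.25, Pvr 0.0215, uif 0.0239, rib 0.28 and sli 0.0860 were gain-of-function averages. comm 0.18, E(spl)mdelta-HLH 0.19, E(spl)malpha-BFM 0.0867, Orc1 -0.0602, aub -0.13, piwi -0.66, tor -0.11, EcR -0.0717 and Nagk -0.13 were gain-of-function averages. CG6180 -0.22, Kr 0.12, Ugt36E1 -0.63, danr 0.26, CG5608 -0.16, CG11263 -0.00509, CG4467 0.37, Or67b 0.01001 and CG7668 -0.21 were gain-of-function averages. CG2767 -0.12, GAPsec -0.14, CG17883 -0.0732, Hsp70Bb 0.46, the neuroblast list 0.11, the tracheal list 0.0847, the midline list 0.0815, the Notch list 0.11 and the added maternal list 0.00115 were gain-of-function averages. gcm 0.19, gcm2 0.28, loco 0.15, Gs2 0.17, Gli 0.14, Nrx-IV 0.0907, nrv2 0.24, yl -0.16 and Marf1 -0.36 were loss-of-function averages. slam -0.17, CG7763 0.14, CG14973 0.14, Prx6b 0.24, NimC4 0.12, Ppn 0.28, Orc1 -0.0296, CycE -0.0794 and cas 0.16 were loss-of-function averages. grk -0.42, piwi -0.62, bnk -0.24, CG31674 0.12, zpg -0.19, gammaTub37C -0.65, Tsp42Ek -0.56, CG8607 -0.13 and slo -0.00930 were loss-of-function averages. NtR 0.23, CG12896 0.40, AOX3 -0.37, Sirup 0.15, Blm -0.45 and the blood cell list 0.12 were loss-of-function averages. AP-2alpha -0.26, CG30440 0.24, htl -0.18, moody -0.19, NimC4 -0.14, BicD 0.16, GstE11 0.55, CycB -0.11 and Septin5 -0.34 were late minus early with ectopic gcm. Spn42Dc -0.27, Cpr67Fa1 0.24, the glial list -0.10, the midline list -0.0967, the cell cycle list -0.12, the Notch list -0.23 and the added maternal list -0.0302 were late minus early with ectopic gcm. TwdlM -0.18, PPO1 0.67, Incenp -0.0115, CG14151 0.60, Ir7c 0.66, the neuroblast list 0.00811, the cell cycle list -0.17 and the Notch list -0.19 were late minus early in the mutants. gcm -0.14, Nagk -0.18, CG31674 -0.0361, zpg 0.11, CG7668 -0.0727, CG2767 -0.0167, GAPsec -0.0108, CG17883 -0.0708 and gammaTub37C 0.51 were the values in gain minus loss. Stage values were Ugt36E1 -1.94 at gain-of-function stage 10, gcm 0.45 at loss-of-function stage 10, Marf1 -0.62 at loss-of-function stage 10 and gcm -0.21 at gain-of-function stage 11. gcm -0.15 at gain-of-function stage 14, gcm 0.69 at loss-of-function stage 14, Vps36 0.9975 at gain-of-function stage 15 and halo -0.61 at loss-of-function stage 13 were further values. gcm2 was 1.06 at loss-of-function stage 13.

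Reversal was judged for genes by the log2 ratio and for lists by the direction of their test. In values turned for the dye, gammaTub37C reversed, at -0.18 in the loss-of-function average with the maternal covariate (adjusted p = 0.838), and the cause was not tested. With that covariate the median of the cell cycle list in the gain-of-function average changed sign, to -0.0483, while its test kept its direction (adjusted p = 0.329). In values not turned, medians changed sign without a reversal for the blood cell list late minus early with ectopic gcm and for the zygotic list of the cellularising embryo in the loss-of-function average.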
